A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

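The series holds 14 Affymetrix Yeast Genome 2.0 arrays of the wild-type strain YSBN6, 1 array per experiment and time. Per the labels' protocols, cells grew in a batch fermentor at 30 °C and pH 5 on glucose with proline, and glutamine was added as a pulse at an OD600 of about 1. Broth was quenched in cold methanol, RNA was extracted with RNeasy, and biotin-labelled cRNA was hybridised. The deposited values are linear intensity values per probe set, 1 column per array. R 2.10.0, the affy package and RMA are named per the submitters' processing notes, and their order and settings are not given in the sources used here. Ranked values were not equal on every array (mean SD of equal-rank log2 values 0.118), so the deposited columns do not share 1 distribution of probe-set values. This does not tell whether the arrays were normalized at an earlier step. The deposited intensity values were turned into log2 here, and nothing else was done to them in the main results.

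The table holds 10928 probe sets. The supplied annotation gives 5498 of them to an S. cerevisiae gene and 1747 to the other yeast on the array (S. pombe), and 3470 are listed for neither. A further 166 are Affymetrix controls and 47 are reporter controls. For 47 genes with more than 1 probe set the brightest was kept, which leaves 5449 genes, and 120 tested probe sets may read several transcripts. For 12 genes the symbol was updated through the gene identifier. The plan was to test every probe set but controls and those of another organism. Because 3470 had no listed gene, the tests cover the 5449 genes, and an alternative chosen after seeing the data adds the rest. The median log2 value of genes was 11.11 ± 0.07 at -10 min, 10.92 ± 0.03 at 7 min and 10.83 ± 0.04 at 24 min (SD, n = 3 arrays). The mean 3-prime minus 5-prime log2 difference of the ACT1 controls was 1.06 ± 0.27, 1.07 ± 0.23 and 1.12 ± 0.24 at these times. The first principal component held 64.7% and the second 14.4% of the variance over genes.

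Tests used limma 3.58.1 in R 4.3.3, and figures used matplotlib 3.10.9 in Python 3.11.15. A model with 1 mean per time was fitted to all 14 arrays with empirical Bayes moderation without trend or robust options (6 residual and 3.31 prior degrees of freedom). Comparisons were 7 against -10 min, 24 against -10 min, 24 against 7 min and an F test over these times. Adjusted p values are from limma with the Benjamini-Hochberg method within each comparison, and a gene is called under 0.05. The 5 times with 1 array were described as differences from the -10 min array of BY008, without a test. Apart from these, limma calls compared each lone array with the mean of the 3 -10 min arrays, assuming the spread of the replicated times. Error values beside log2 fold changes are standard errors from the pooled fit.

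The 39 gene lists cover nitrogen use, translation, amino acid and nucleotide synthesis, stress, energy, the cell cycle, other cell states and reference genes, as named one by one in the results. Each list with at least 4 measured members was tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists) and with fry, and with camera using an estimated correlation. List medians are relative to the median of all genes. Counts "adjusted over the list alone" adjust the gene p values within the list. Lists, tests, comparisons, the rule for naming genes and most alternatives were chosen before the data were examined. Chosen after seeing the data were 4 alternatives: the added probe sets, leaving out the -10 min array of BY012 for the lists and for the times with 1 array, and values at 56 min beside those at 120 min. That rule names the 10 largest rises and 10 largest falls with 1 sign in all 3 experiments, up to 4 called members of each list with the largest changes, the 5 largest rises and falls at each single time among brighter genes, and 20 fixed genes. Examples in the text are drawn from these.

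The labels give each array 1 of 3 experiment codes, and on that basis the alternative with a block pairs the arrays of 1 experiment, which the main results do not. The labels do not say that 1 culture was sampled at several times. Deviations of genes from the time means correlated between -10 and 7, -10 and 24, and 7 and 24 min with r = 0.63, 0.36 and 0.35 in BY008, 0.08, -0.05 and 0.21 in BY003, and 0.56, 0.08 and 0.44 in BY012. Experiment as a replicate block was an alternative, as were a random block, subtraction of array medians, quantile normalization, a filter on dim genes, trend and robust options, stricter thresholds, the mean over probe sets, and leaving out each experiment and each array. Tested on simulated data with 200 changed genes of 5449, the fit called 2 of 67 genes with a log2 change of 0.5, 43 of 67 with 1 and 66 of 66 with 2, and 2.63% of its calls were false. In a separate simulated data set camera called the shifted list and 1 unshifted list of 39. The simulated noise was independent between genes and between arrays, with no shared effect of experiment. These rates therefore need not hold for the real arrays, where deviations were shared within experiments. All 14 columns were used, and the raw image files are not analysed here. The highest log2 value was 15.14, and 94 genes had a mean within 1 of it at -10 min, 18 of them among the 127 cytosolic ribosomal protein genes. Changes of such bright genes may be compressed, which the deposited values cannot settle.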

Results

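The series followed a wild-type budding yeast, strain YSBN6, through a change of nitrogen source. Cells grew in a batch fermentor on glucose with proline, a poor nitrogen source, until a pulse of glutamine, a preferred one, was added. The design text compares the times after the pulse with the steady state, here called -10 min. RNA was measured on 14 arrays, 1 per experiment and time. The times -10, 7 and 24 min had 3 arrays each, from experiments BY003, BY008 and BY012. The times 3, 10, 14, 56 and 120 min had 1 array each, all from BY008, so their values have no replicates. The median intensity per array over all probe sets lay between 159 and 279, and the number of arrays limits the precision. Over genes, which are not independent replicates, arrays of 1 time correlated with r from 0.928 to 0.985. The -10 min array of BY012 stood apart, with 32 genes at least 4-fold above and 11 at least 4-fold below both other -10 min arrays. Its deviation is given below beside the gene lists that deviated most in it. Leaving out that array alone was planned for the gene counts of replicated times, and for the lists it was chosen after seeing the data. The 5449 genes with a listed S. cerevisiae gene were tested, and 4001 of them changed over the 3 replicated times (limma, moderated F test), or 2476 without BY003.

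At 7 min, genes for making ribosomes rose and genes for using poor nitrogen sources fell. The RNA helicase gene DBP2 rose 21.1-fold (log2 fold change 4.40 ± 0.40, SE, n = 3 arrays per time) and NSR1, for the nucleolar protein nucleolin, rose 20.9-fold (4.39 ± 0.35). All 128 ribosome biogenesis genes measured rose (128 adjusted over the list alone). The largest falls included BDH2 (-3.78 ± 0.27), SHH4 (-3.59 ± 0.39), SDP1 (-3.36 ± 0.45), RTS3 (-3.36 ± 0.23) and WSC4 (-3.33 ± 0.25), where SDP1 encodes a phosphatase of the Slt2 kinase and WSC4 a sensor of the cell wall. Other large rises were GFD2 (4.14 ± 0.26), ATC1 (3.87 ± 0.27) and SYO1 (3.76 ± 0.22), and TOD6, for a repressor of ribosome biogenesis genes, rose 15.9-fold. The highest adjusted p among these genes was 0.000331 (limma).

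Nitrogen genes moved mostly down at 7 min. In the nitrogen catabolite repression list, genes shut off when a good nitrogen source is present, 28 of 40 fell (29 adjusted over the list alone), with examples RTS3 (-3.36 ± 0.23), ATG14 (-3.08 ± 0.29), YGK3 (-2.75 ± 0.31) and DAL80 (-2.74 ± 0.21). Its median change was -0.93 on the log2 scale relative to the median of all genes (camera, adjusted p = 1.68e-05, and adjusted p = 0.590 with an estimated correlation). Of the proline utilisation genes, 3 of 4 fell (3 adjusted over the list alone), median -1.33, adjusted p = 0.137, adjusted p = 0.711 with an estimated correlation. The proline oxidase gene PUT1 fell (-2.65 ± 0.24), as did the permease gene PUT4 (-1.77 ± 0.30) and the dehydrogenase gene PUT2 (-1.56 ± 0.31). Of the genes for allantoin and urea use, 7 of 10 fell (9 adjusted over the list alone), median -0.92, adjusted p = 0.0277, adjusted p = 0.724 with an estimated correlation. Its medians were -0.12 in BY003, -1.16 in BY008 and -1.37 in BY012. That call was lost without BY008 (adjusted p = 0.0521) or without BY012 (adjusted p = 0.0810, and from 0.00289 to 0.0810 over the alternatives with the preset correlation). GAP1, for the general amino acid permease, fell (-1.38 ± 0.23, adjusted p = 0.00119), and so did GAT1, for a GATA activator (-0.95 ± 0.21). The urea transporter gene DUR3 was at -1.29 ± 0.54 (adjusted p = 0.0701, and 0.0372 with experiment as a block), and the allantoate permease gene DAL5 at -0.48 ± 0.24 (adjusted p = 0.121). DAL5 started at a mean log2 intensity of 14.60, close to the highest value of any probe set (15.14), where a change may be compressed. PUT1 started at 14.61 and its fall of -2.65 was seen. A large fall can show despite compression, so this does not settle the question for DAL5. GAT1 was not called without BY003 (adjusted p = 0.0943) or without BY008 (0.0502), and PUT2 not without BY003 (0.0580).

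Among the genes of central nitrogen metabolism 2 of 5 fell (2 adjusted over the list alone), and the list had median 0.09, adjusted p = 0.747, adjusted p = 0.784 with an estimated correlation, with its mean and test on the lower side. It stood at -0.65 in the -10 min array of BY012. GDH2, for the glutamate dehydrogenase that releases ammonium, was at -1.40 ± 0.45, GLN1, for glutamine synthetase, at -0.70 ± 0.23, and MEP2, for an ammonium permease, at -0.59 ± 0.15, and these 3 calls ended once array medians were subtracted. Without BY003 their adjusted p values were 0.189, 0.228 and 0.0752, and without BY012 those of GDH2 and GLN1 were 0.0570 and 0.0553. GDH1 (0.43 ± 0.38) and GLT1 (-0.21 ± 0.19), for glutamate synthesis, did not pass the test. URE2, for the protein that holds Gln3 in the cytoplasm, rose (0.63 ± 0.15, adjusted p = 0.00727, or 0.0625 without BY003), whereas GLN3 stood at 0.14 ± 0.19. GCN4, for the activator of amino acid synthesis, stood at 0.00 ± 0.11, or 0.20 once array medians were subtracted. It started at 14.50 on the log2 scale, close to the highest value of 15.14, so a rise may be hidden. Of the amino acid permeases under the SPS sensor 3 rose and 2 fell out of 8 (3 and 2 adjusted over the list alone), median 0.46, adjusted p = 0.154, adjusted p = 0.711 with an estimated correlation, with rises of GNP1 (2.21 ± 0.30) and TAT2 (1.55 ± 0.21) and a fall of DIP5 (-2.49 ± 0.48), while AGP1 was at 0.16 ± 0.36. Of the retrograde response genes 1 rose and 1 fell out of 9 (1 and 1 adjusted over the list alone), median 0.47, adjusted p = 0.400, adjusted p = 0.763 with an estimated correlation, and it stood at 0.41 in that array. ATO3, for an ammonium exporter, rose (2.24 ± 0.26), and CIT2, for peroxisomal citrate synthase, stood at -0.58 ± 0.22 (adjusted p = 0.0534, and 0.0152 with experiment as a block).

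Genes for translation moved up at 7 min. The ribosome biogenesis list had median 2.93, adjusted p = 3.17e-64, adjusted p = 0.583 with an estimated correlation, with rises of DRS1 (3.86 ± 0.32), PWP2 (3.75 ± 0.23) and MAK16 (3.74 ± 0.24). In the list for RNA polymerases I and III, which make ribosomal and transfer RNA, 19 of 19 rose (19 adjusted over the list alone), median 2.30, adjusted p = 1.93e-14, adjusted p = 0.583 with an estimated correlation. Among them were RPA49 (3.77 ± 0.32) and RPA43 (3.08 ± 0.33). Of the translation factors 24 of 33 rose (26 adjusted over the list alone), median 1.29, adjusted p = 6.54e-13, adjusted p = 0.590 with an estimated correlation. Examples are NIP1 (2.08 ± 0.19) and TIF4631 (1.81 ± 0.16). Of the aminoacyl-tRNA synthetase genes 14 of 20 rose (15 adjusted over the list alone), median 1.07, adjusted p = 5.44e-07, adjusted p = 0.711 with an estimated correlation, KRS1 (1.41 ± 0.25) and MES1 (1.40 ± 0.18) among them. Of the cytosolic ribosomal protein genes 66 of 127 rose (66 adjusted over the list alone), median 0.81, adjusted p = 1.50e-19, adjusted p = 0.724 with an estimated correlation. Among them were RPL22B (2.13 ± 0.18) and RPS9A (1.87 ± 0.25). Once array medians were subtracted, 110 of these 127 were called as risen and 0 as fallen. Their medians were 0.48 in BY003, 0.57 in BY008 and 1.32 in BY012, and those of the synthetases 0.85, 0.62 and 1.63. In the -10 min array of BY012 the ribosomal protein genes stood at -0.69 against the other -10 min arrays, the synthetases at -0.88, the polymerases at -0.71, the translation factors at -0.49 and ribosome biogenesis at -0.35. Of the mitochondrial ribosomal protein genes, by contrast, 1 rose and 38 fell out of 66 (1 and 38 adjusted over the list alone), median -0.11, adjusted p = 0.00464, adjusted p = 0.763 with an estimated correlation. Examples are MRP2 (-1.26 ± 0.19) and MRP49 (-1.12 ± 0.14), and 3 rose and 24 fell once array medians were subtracted.

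Among the nucleotide genes, 11 rose and 0 fell out of 19 (11 and 1 adjusted over the list alone) for purine and one-carbon synthesis, median 1.26, adjusted p = 5.19e-05, adjusted p = 0.724 with an estimated correlation, and 5 rose and 1 fell out of 10 (5 and 1 adjusted over the list alone) for pyrimidines, median 0.78, adjusted p = 0.00685, adjusted p = 0.590 with an estimated correlation. IMD4, for a step of guanine nucleotide synthesis, rose (3.61 ± 0.26), as did URA7, for CTP synthase (3.52 ± 0.30). Of the branched-chain amino acid genes 7 of 11 rose (7 adjusted over the list alone), median 0.98, adjusted p = 0.00670, adjusted p = 0.724 with an estimated correlation, with a rise of LEU9 (2.51 ± 0.33). For serine, threonine and aspartate 3 rose and 1 fell out of 11 (3 and 0 adjusted over the list alone), median 1.12, adjusted p = 0.0300, adjusted p = 0.763 with an estimated correlation. The call was lost once array medians were subtracted (adjusted p = 0.0673) or without the -10 min array of BY012 (0.0993, and from 0.0127 to 0.0993 over the alternatives with the preset correlation). Of the sulfur amino acid genes 5 of 23 rose (0 adjusted over the list alone), median 1.37, adjusted p = 0.000529, adjusted p = 0.759 with an estimated correlation, the methionine permease gene MUP1 among them (3.15 ± 0.81). The sulfur medians were 0.04 in BY003, 1.18 in BY008 and 2.82 in BY012. In the same order they were 0.93, 0.71 and 1.89 for the purine genes, 0.63, 0.44 and 1.18 for the pyrimidine genes and 0.62, 0.46 and 1.86 for the serine family. In the -10 min array of BY012 the sulfur genes stood at -1.98 against the other -10 min arrays, the serine family at -1.21, the purine genes at -0.96 and the branched-chain genes at -0.83. MUP1 was not called without BY008 (adjusted p = 0.0924) or without BY012 (0.0996). Of the hexose transporter genes 4 of 6 rose (4 adjusted over the list alone), median 1.14, adjusted p = 0.00627, adjusted p = 0.583 with an estimated correlation. Among them were HXT4 (3.03 ± 0.30) and HXT2 (1.69 ± 0.23).

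Genes for stress, self-digestion and protein breakdown moved down at 7 min. Of the genes induced in the environmental stress response 23 of 38 fell (23 adjusted over the list alone), median -0.92, adjusted p = 0.000631, adjusted p = 0.763 with an estimated correlation. Examples are HSP42 (-2.96 ± 0.30) and GLC3 (-2.90 ± 0.47), for a small heat shock protein and the glycogen branching enzyme. That list stood at 0.90 in the -10 min array of BY012. Of the autophagy genes 14 of 19 fell (14 adjusted over the list alone), median -1.18, adjusted p = 0.000964, adjusted p = 0.711 with an estimated correlation. Among them were ATG7 (-3.25 ± 0.27) and ATG14 (-3.08 ± 0.29), and their deviation in that array was 0.48. Of the proteasome genes 23 of 33 fell (27 adjusted over the list alone), median -0.32, adjusted p = 0.00395, adjusted p = 0.763 with an estimated correlation, led by RPN4, for the activator of proteasome genes (-1.61 ± 0.29), and 5 fell once array medians were subtracted. The proteasome medians were -0.25 in BY003, -0.14 in BY008 and -0.51 in BY012. Of the chaperone genes 1 rose and 11 fell out of 18 (1 and 11 adjusted over the list alone), median -0.25, adjusted p = 0.0511, adjusted p = 0.724 with an estimated correlation. That list was called once array medians were subtracted (adjusted p = 0.0447), without BY008 (0.0429) or without BY012 (0.0462, and from 0.0429 to 0.0790 over the alternatives with the preset correlation). HSP82 fell (-1.58 ± 0.24). Of the TCA cycle genes 9 of 15 fell (9 adjusted over the list alone), median -0.19, adjusted p = 0.365, adjusted p = 0.784 with an estimated correlation, with SDH1 at -0.86 ± 0.22 (adjusted p = 0.0756 without BY003), and 3 fell once array medians were subtracted. The list stood at 0.44 in that array. Of the cyclin and replication genes for entry into S phase 1 rose and 7 fell out of 14 (1 and 7 adjusted over the list alone), median -0.67, adjusted p = 0.222, adjusted p = 0.784 with an estimated correlation. With experiment as a block that list was called (adjusted p = 0.0333, 11 members fell, and from 0.0333 to 0.246 over the alternatives with the preset correlation). So was the list for G2 to M (adjusted p = 0.0333, 7 fell, and from 0.00709 to 0.232 over the alternatives with the preset correlation), for which, without the block, 3 of 9 fell (2 adjusted over the list alone), median -0.78, adjusted p = 0.163, adjusted p = 0.784 with an estimated correlation. In the -10 min array of BY012 these lists stood at -0.68 and -0.91. The cyclin gene CLN1 fell (4.28-fold), whereas CLN3 was at 0.30 ± 0.30.

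The comparison of 7 with -10 min called 2857 of 5449 genes, 910 higher and 1947 lower. Over all 5449 genes, called or not, 82.3% had 1 sign in all 3 experiments, against 25% by chance with no shift of the median gene. The median of all genes shifted by -0.33, so the split depends on scaling: it was 1158 higher and 1320 lower once array medians were subtracted, and 1122 higher and 1395 lower after quantile normalization. Of the 39 lists, camera called 17, 11 higher and 6 lower, and fry called 21. With an estimated correlation camera called 0 (adjusted p from 0.583 to 0.977), and 3 had an unadjusted p under 0.05. Without BY003, 1373 genes were called, and 50 of the 144 called named genes were lost.

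**Figure D1:**
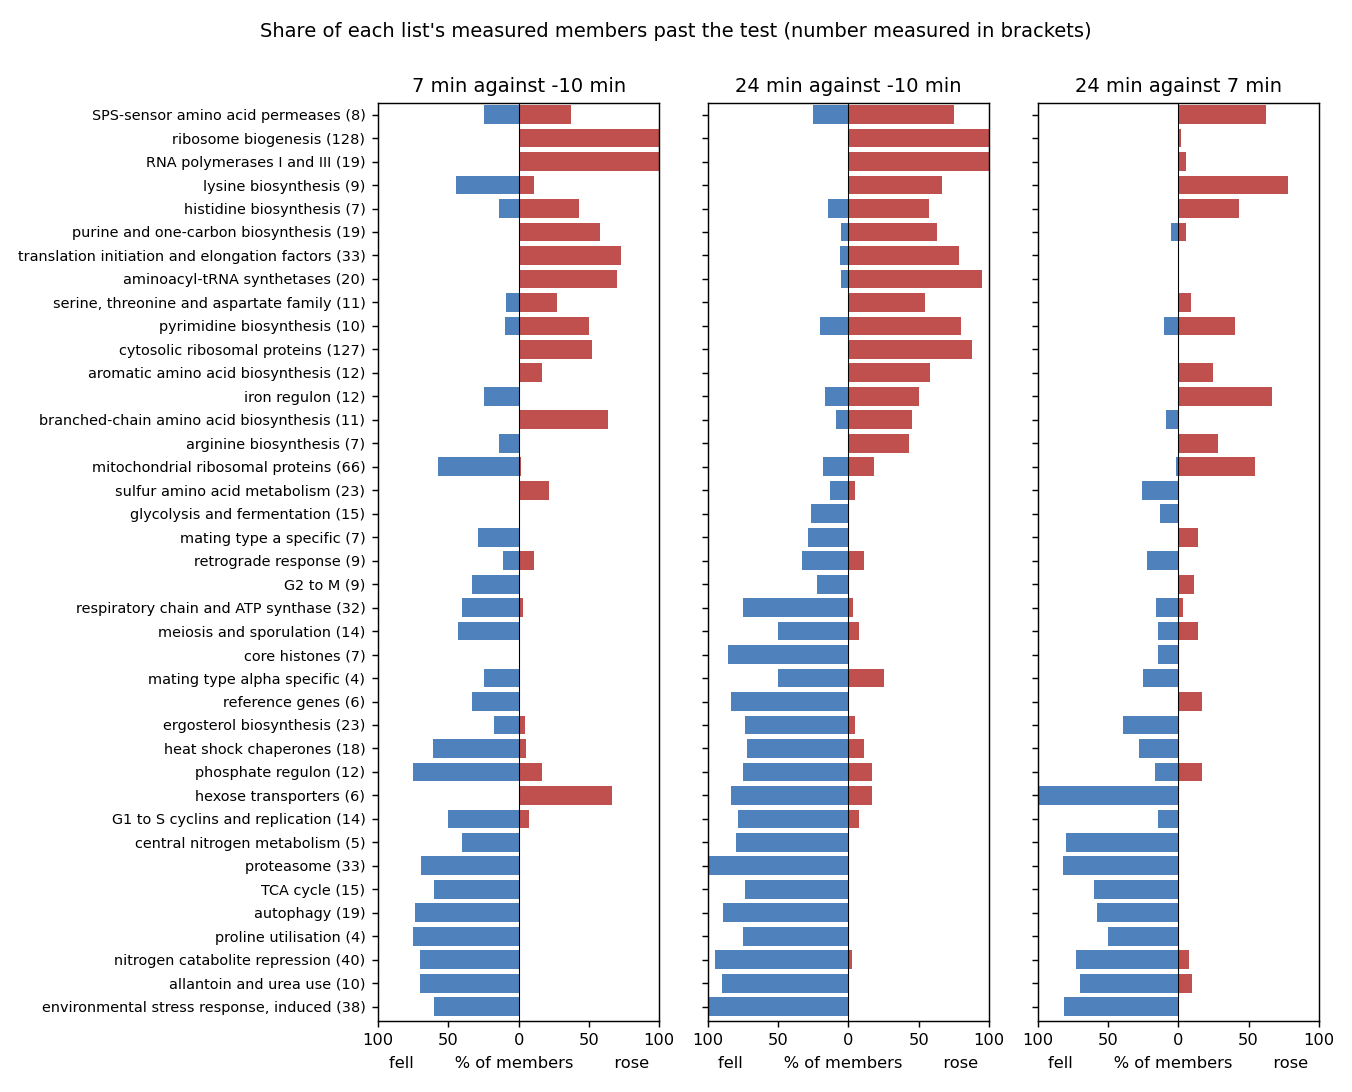
Each bar gives the percent of a list's measured members that rose (right) or fell (left) in 1 of the 3 comparisons of replicated times (limma, n = 3 arrays per time), with lists ordered by their median at 24 against -10 min. All 128 ribosome biogenesis genes rose at 7 and at 24 min; once array medians were subtracted the mitochondrial ribosomal protein genes turned from 12 rises and 12 falls to 28 and 7 at 24 min.

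At 24 min the rise of ribosome genes stood beside a rise of amino acid permeases and deeper falls of nitrogen, stress and protein breakdown genes. BAP2, for a branched-chain amino acid permease, rose 27.5-fold and TAT2, for a tryptophan permease, rose 24.0-fold, with log2 fold changes of 4.78 ± 0.21 and 4.58 ± 0.21 (SE, n = 3 arrays per time). The phosphate transporter gene PHO84 rose too (4.16 ± 0.48), beside PRM7 (4.46 ± 0.20) and DUS3 (4.10 ± 0.32). CYC7, for a minor cytochrome c, fell the most (-5.73 ± 0.35), with GPM2 (-5.53 ± 0.19), EMI2 (-5.17 ± 0.23), UBC8 (-4.90 ± 0.23), AMS1 (-4.82 ± 0.25) and RNY1 (-4.73 ± 0.21) among the largest falls. AMS1 encodes a mannosidase and RNY1 a ribonuclease of the vacuole. Adjusted p values of these genes were at most 5.69e-05 (limma).

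For the nitrogen catabolite repression list 1 rose and 38 fell out of 40 (1 and 38 adjusted over the list alone), median -2.26, adjusted p = 1.48e-08, adjusted p = 0.537 with an estimated correlation. Examples are DAL4 (-4.47 ± 0.47), UGX2 (-4.46 ± 0.39) and UGA1 (-4.10 ± 0.32), of which UGA1 encodes a transaminase of GABA use. Of the allantoin and urea genes 9 of 10 fell (9 adjusted over the list alone), median -2.62, adjusted p = 0.00503, adjusted p = 0.537 with an estimated correlation. Examples are DAL7 (-3.54 ± 0.36), DAL80 (-3.44 ± 0.21) and DAL5 (-3.26 ± 0.24). Of the proline genes 3 of 4 fell (3 adjusted over the list alone), median -2.26, adjusted p = 0.202, adjusted p = 0.537 with an estimated correlation, namely PUT4 (-3.52 ± 0.30), PUT2 (-2.61 ± 0.31) and PUT1 (-2.58 ± 0.24). The other permease genes fell as well, GAP1 (-2.27 ± 0.23), MEP2 (-3.41 ± 0.15) and DUR3 (-2.65 ± 0.54), and GAT1 fell (-1.67 ± 0.21). GAP1 went from a mean log2 intensity of 14.49 ± 0.07 to 12.23 ± 0.22 (SD, n = 3 arrays), and MEP2 from 14.81 ± 0.06 to 11.40 ± 0.12. GLN3, for the other GATA activator, rose (1.11 ± 0.19, adjusted p = 0.000582), as did URE2 (0.73 ± 0.15). Of the central nitrogen genes 4 of 5 fell (4 adjusted over the list alone), median -1.16, adjusted p = 0.147, adjusted p = 0.537 with an estimated correlation, with falls of GLN1 (-1.49 ± 0.23) and GLT1 (-1.13 ± 0.19) and of GDH2 (from a mean log2 intensity of 13.64 ± 0.54 to 10.64 ± 0.19, SD). GDH1 did not pass the test at -0.11 ± 0.38, which turned to 0.17 once array medians were subtracted, and GCN4 was at -0.17 ± 0.11, which turned to 0.11. CIT2 fell (-0.94 ± 0.22), and in the retrograde list 1 rose and 3 fell out of 9 (1 and 3 adjusted over the list alone), median -0.02, adjusted p = 0.755, adjusted p = 0.860 with an estimated correlation. In the -10 min array of BY012 the central nitrogen list stood at -0.65 and the retrograde list at 0.41.

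Of the permeases under the SPS sensor 6 rose and 2 fell out of 8 (6 and 2 adjusted over the list alone), median 3.68, adjusted p = 0.00431, adjusted p = 0.537 with an estimated correlation. Among them were BAP3 (3.92 ± 0.27) and AGP1 (3.78 ± 0.36). BAP3 lay within the range of probe sets of another organism at -10 min, so its fold is uncertain. Of the lysine genes 6 rose and 0 fell out of 9 (7 and 1 adjusted over the list alone), median 1.75, adjusted p = 0.00308, adjusted p = 0.537 with an estimated correlation. Examples are LYS4 (2.14 ± 0.22) and LYS12 (1.87 ± 0.20). Of the histidine genes, 4 rose and 1 fell out of 7 (4 and 1 adjusted over the list alone), median 1.36, adjusted p = 0.0343, adjusted p = 0.537 with an estimated correlation. The call was lost once array medians were subtracted (adjusted p = 0.0688), without BY012 (0.0711) and without its -10 min array (0.0501, and from 0.0118 to 0.0711 over the alternatives with the preset correlation). Of the aromatic genes 7 of 12 rose (7 adjusted over the list alone), median 0.93, adjusted p = 0.00631, adjusted p = 0.589 with an estimated correlation, with a rise of ARO2 (1.63 ± 0.22). Of the branched-chain genes, 5 rose and 1 fell out of 11 (5 and 1 adjusted over the list alone), median 0.79, adjusted p = 0.0183, adjusted p = 0.589 with an estimated correlation, with LEU9 at 2.97 ± 0.33 and BAT2 at -2.47 ± 0.53, and of the serine family, 6 of 11 rose (6 adjusted over the list alone), median 1.25, adjusted p = 0.0183, adjusted p = 0.589 with an estimated correlation. The calls of these last lists were lost without BY012 (adjusted p = 0.0526 for each, and from 0.00330 to 0.0526 for the branched-chain list and from 0.00591 to 0.0526 over the alternatives with the preset correlation for the serine family). Of the arginine genes, 3 of 7 rose (3 adjusted over the list alone), median 0.46, adjusted p = 0.204, adjusted p = 0.699 with an estimated correlation. ARG2 rose (1.16 ± 0.25). The medians in BY003, BY008 and BY012 were 0.86, 0.59 and 2.50 for the histidine genes, 0.75, 0.38 and 1.84 for the aromatic, 0.79, 0.32 and 1.28 for the branched-chain, 0.60, 0.60 and 2.25 for the serine family and 0.24, 0.13 and 1.99 for the arginine genes, highest in BY012 each time. In the -10 min array of BY012 the aromatic genes stood at -0.87, the branched-chain genes at -0.83, the histidine genes at -0.79, the arginine genes at -0.50 and the serine family at -1.21 against the other -10 min arrays. Of the sulfur genes, 1 rose and 3 fell out of 23 (0 and 2 adjusted over the list alone), median 0.26, adjusted p = 0.539, adjusted p = 0.899 with an estimated correlation. The list had medians of -0.95 in BY003, -0.59 in BY008 and 2.43 in BY012. Their pooled median turned to -0.80 without BY012 and to -0.48 without its -10 min array, in which they stood at -1.98.

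All 128 ribosome biogenesis genes rose again (128 adjusted over the list alone, median 3.20, adjusted p = 1.56e-44, adjusted p = 0.537 with an estimated correlation), for example NSR1 (4.04 ± 0.35), DRS1 (4.03 ± 0.32) and DBP3 (3.87 ± 0.33). Among the other translation lists, 19 of 19 rose (19 adjusted over the list alone) for the polymerases (median 2.32, adjusted p = 3.21e-10, adjusted p = 0.537 with an estimated correlation), 26 rose and 2 fell out of 33 (27 and 2 adjusted over the list alone) for translation factors (median 1.35, adjusted p = 6.01e-09, adjusted p = 0.537 with an estimated correlation) and 19 rose and 1 fell out of 20 (19 and 1 adjusted over the list alone) for the synthetases (median 1.27, adjusted p = 3.85e-06, adjusted p = 0.537 with an estimated correlation). Of the cytosolic ribosomal protein genes 112 of 127 rose (117 adjusted over the list alone), median 0.97, adjusted p = 6.01e-18, adjusted p = 0.537 with an estimated correlation, with a rise of RPL9A (2.15 ± 0.44). Their medians were 0.68 in BY003, 0.74 in BY008 and 1.46 in BY012, and the deviations of the -10 min array of BY012 were -0.69 for these genes, -0.88 for the synthetases, -0.71 for the polymerases, -0.49 for the translation factors and -0.96 for the purine list. Of the mitochondrial ribosomal protein genes, 12 rose and 12 fell out of 66 (7 and 10 adjusted over the list alone), median 0.32, adjusted p = 0.183, adjusted p = 0.827 with an estimated correlation, a split that turned to 28 rises and 7 falls once array medians were subtracted, when the list was called as higher (adjusted p = 0.0222, and from 0.0222 to 0.356 over the alternatives with the preset correlation). MRP8, first named a mitoribosomal gene from its sequence, fell (-2.66 ± 0.22), and MRPL17 rose (0.92 ± 0.13). Of the purine genes, 12 rose and 1 fell out of 19 (12 and 1 adjusted over the list alone), median 1.35, adjusted p = 0.000187, adjusted p = 0.537 with an estimated correlation. Among them were IMD4 (3.77 ± 0.26) and ADE8 (1.74 ± 0.25), and the list medians were 1.23 in BY003, 0.84 in BY008 and 2.22 in BY012. Of the pyrimidine genes, 8 rose and 2 fell out of 10 (8 and 2 adjusted over the list alone), median 1.23, adjusted p = 0.00503, adjusted p = 0.537 with an estimated correlation. Examples are URA7 (3.69 ± 0.30) and URA10 (-2.78 ± 0.37).

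All 38 stress response genes fell (38 adjusted over the list alone, median -3.24, adjusted p = 4.82e-09, adjusted p = 0.537 with an estimated correlation), as did all 33 proteasome genes (33 adjusted over the list alone, median -1.22, adjusted p = 7.10e-07, adjusted p = 0.589 with an estimated correlation). Examples are SOL4 (-4.59 ± 0.40), GPH1, for glycogen phosphorylase (-4.28 ± 0.53), and the core subunit genes PRE3 (-2.92 ± 0.27) and PUP3 (-2.84 ± 0.35). The stress list stood at 0.90, the autophagy list at 0.48 and the TCA cycle list at 0.44 in the -10 min array of BY012. Of the autophagy genes 17 of 19 fell (17 adjusted over the list alone), median -2.21, adjusted p = 0.000193, adjusted p = 0.537 with an estimated correlation. ATG7 (-4.29 ± 0.27) and ATG4 (-3.60 ± 0.32) fell. Of the TCA cycle genes 11 of 15 fell (11 adjusted over the list alone), median -1.51, adjusted p = 0.00503, adjusted p = 0.537 with an estimated correlation. Among them were CIT1 (-2.66 ± 0.25), KGD2 (-2.39 ± 0.16) and SDH1 (-2.23 ± 0.22). Of the respiratory chain genes, 1 rose and 24 fell out of 32 (1 and 24 adjusted over the list alone), median -0.24, adjusted p = 0.0535, adjusted p = 0.733 with an estimated correlation, called with experiment as a block (adjusted p = 0.0243, and from 0.0243 to 0.146 over the alternatives with the preset correlation). NDI1 fell (-1.76 ± 0.19) while CYC1 rose (1.72 ± 0.18). Of the chaperone genes, 2 rose and 13 fell out of 18 (2 and 13 adjusted over the list alone), median -0.53, adjusted p = 0.0276, adjusted p = 0.537 with an estimated correlation. Examples are HSP104 (-3.08 ± 0.23) and SSA1 (-2.18 ± 0.15), and the list medians were -0.28 in BY003, -0.62 in BY008 and -0.79 in BY012. Of the ergosterol genes 1 rose and 17 fell out of 23 (1 and 17 adjusted over the list alone), median -0.47, adjusted p = 0.0343, adjusted p = 0.590 with an estimated correlation. Among them were ERG28 (-2.42 ± 0.24) and HMG2 (-2.02 ± 0.18). Of the glycolysis genes, 4 of 15 fell (4 adjusted over the list alone), median 0.18, adjusted p = 0.539, adjusted p = 0.856 with an estimated correlation, with the mean and test on the lower side, and ENO1 fell (-0.90 ± 0.13).

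Several cell cycle genes fell at 24 min. Of the S phase entry genes 1 rose and 11 fell out of 14 (1 and 12 adjusted over the list alone), median -1.09, adjusted p = 0.0697, adjusted p = 0.699 with an estimated correlation, called with experiment as a block (adjusted p = 0.00841, and from 0.00841 to 0.0943 over the alternatives with the preset correlation). RFA1, for a single-strand DNA binding protein, fell (-2.83 ± 0.46), as did the cyclin gene CLN2 (-2.12 ± 0.36), and CLN3 was called at -0.77 ± 0.30, a call lost under both scaling alternatives, without BY003 (adjusted p = 0.253) and without BY008 (0.169). Of the core histone genes 6 of 7 fell (6 adjusted over the list alone), median -0.40, adjusted p = 0.208, adjusted p = 0.733 with an estimated correlation, called without BY008 (adjusted p = 0.0428, and from 0.0428 to 0.347 over the alternatives with the preset correlation). Of the G2 to M genes 2 of 9 fell (0 adjusted over the list alone), median -0.12, adjusted p = 0.769, adjusted p = 0.904 with an estimated correlation, with 4 falls with experiment as a block. In the -10 min array of BY012 the S phase entry genes stood at -0.68 and the G2 to M genes at -0.91. Of the hexose transporters, 1 rose and 5 fell out of 6 (1 and 5 adjusted over the list alone), median -1.06, adjusted p = 0.253, adjusted p = 0.589 with an estimated correlation. Examples are HXT5 (-3.65 ± 0.66) and HXT3 (-1.45 ± 0.15). Of the phosphate genes, 2 rose and 9 fell out of 12 (2 and 9 adjusted over the list alone), median -0.58, adjusted p = 0.271, adjusted p = 0.590 with an estimated correlation. Of the iron genes, 6 rose and 2 fell out of 12 (6 and 2 adjusted over the list alone), median 0.90, adjusted p = 0.0640, adjusted p = 0.607 with an estimated correlation, with a rise of FRE1 (2.23 ± 0.37). That list was called without BY003 (adjusted p = 0.0347) or BY012 (0.0257, and from 0.0257 to 0.186 over the alternatives with the preset correlation). Markers of other cell states were checked alike. Of the meiosis genes, 1 rose and 7 fell out of 14 (1 and 7 adjusted over the list alone), median -0.31, adjusted p = 0.400, adjusted p = 0.733 with an estimated correlation. Of the genes specific to mating type a, 2 of 7 fell (2 adjusted over the list alone), median 0.11, adjusted p = 0.786, adjusted p = 0.904 with an estimated correlation, with the mean and test on the lower side, and of the genes specific to mating type alpha, 1 rose and 2 fell out of 4 (1 and 2 adjusted over the list alone), median -0.44, adjusted p = 0.781, adjusted p = 0.856 with an estimated correlation. The mating type a list stood at -0.45 in the -10 min array of BY012, and its median turned to -0.21 without that array. SPS4 fell (-2.55 ± 0.35) and so did SAG1 (-1.46 ± 0.22). Of the reference genes 5 of 6 fell (5 adjusted over the list alone), median -0.44, adjusted p = 0.365, adjusted p = 0.733 with an estimated correlation. ACT1 was called at -0.40 ± 0.14 but not once array medians were subtracted, nor without BY003 (adjusted p = 0.162), BY008 (0.0738) or BY012 (0.0606). At 7 min it stood at -0.18 ± 0.14, which turned to 0.014 under that scaling.

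This comparison called 3756 genes, 1312 higher and 2444 lower. Of all genes, called or not, 83.1% had 1 sign in all 3 experiments. The all-gene median shifted by -0.33, and the split became 1738 higher and 1938 lower once array medians were subtracted and 1805 higher and 1796 lower after quantile normalization. Camera called 21 of the 39 lists, 13 higher and 8 lower, and fry called 32. With an estimated correlation camera called 0 (adjusted p from 0.537 to 0.904), and 2 had an unadjusted p under 0.05. Of the 169 called named genes, 21 were lost without BY003, 10 without BY008 and 13 without BY012.

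**Figure D2:**
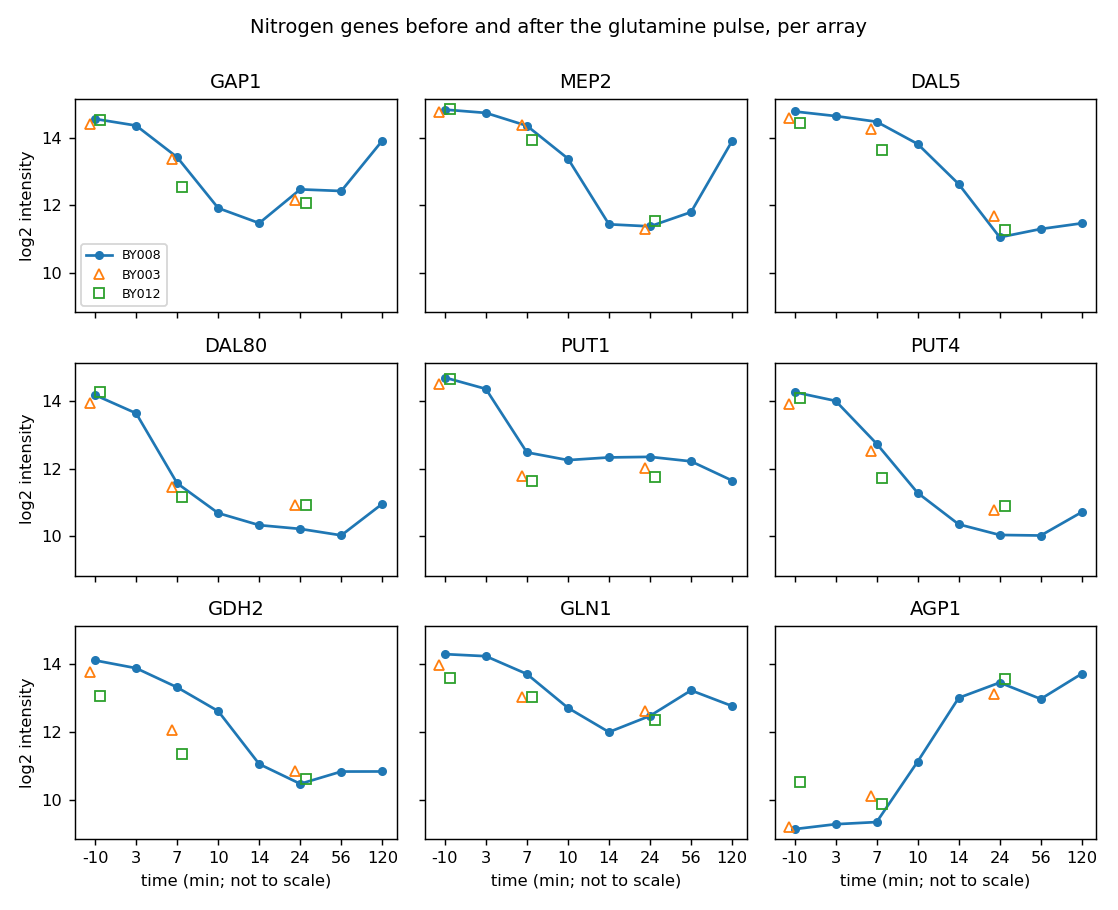
Log2 intensity of 9 nitrogen genes on each array against time (spacing not to scale), with BY008 as filled circles joined by a line and BY003 and BY012 as open symbols. GAP1 falls from 14.49 ± 0.07 at -10 min to 12.23 ± 0.22 at 24 min (mean ± SD, n = 3), and AGP1 goes from 9.61 ± 0.79 to 13.39 ± 0.23.

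Between 7 and 24 min, amino acid permeases and lysine genes rose, whereas stress, proteasome and hexose transporter genes fell. BAP2 (3.81 ± 0.21) and AGP1 (3.62 ± 0.36) were among the largest rises, given as log2 fold change ± SE with n = 3 arrays per time. BAP3 stood at 3.85 ± 0.27, but its mean log2 intensity at 7 min, 6.14, was close to the dim bound of 6.11, so its fold is uncertain. Others were HSP30, for a stress protein of the plasma membrane (3.63 ± 0.45), YPS3, for a cell surface protease (3.60 ± 0.23), NRG1, for a repressor of glucose-repressed genes (3.56 ± 0.39), and PDR12, for a pump of weak acids (2.97 ± 0.17). The largest fall was that of MTH1, for a repressor of hexose transporter genes (-4.69 ± 0.36), ahead of COS111 (-4.51 ± 0.29), GPM2 (-4.28 ± 0.19), EMI2 (-4.20 ± 0.23), TMA10 (-4.08 ± 0.32) and STF2 (-3.83 ± 0.27). The highest adjusted p of these genes was 0.000450 (limma).

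Of the permeases under the SPS sensor, 5 of 8 rose (5 adjusted over the list alone), median 2.41, adjusted p = 0.000431, adjusted p = 0.233 with an estimated correlation. Of the lysine genes 7 of 9 rose (8 adjusted over the list alone), median 1.57, adjusted p = 9.43e-06, adjusted p = 0.336 with an estimated correlation. Among them were LYS20 (2.64 ± 0.26), LYS1 (2.51 ± 0.27) and LYS2 (1.72 ± 0.26). At 7 against -10 min the lysine list had 1 gene that rose and 4 that fell out of 9 (2 and 4 adjusted over the list alone), median 0.05, adjusted p = 0.907, adjusted p = 0.966 with an estimated correlation, with the mean and test on the lower side, and LYS20 was called at -0.89 ± 0.26, a call lost without BY003 (adjusted p = 0.137) and without BY012 (0.0849). Of the histidine genes, 3 of 7 rose (3 adjusted over the list alone), median 0.44, adjusted p = 0.0829, adjusted p = 0.722 with an estimated correlation, called without BY008 (adjusted p = 0.0141, and from 0.0141 to 0.193 over the alternatives with the preset correlation). Of the aromatic genes, 3 of 12 rose (1 adjusted over the list alone), median 0.40, adjusted p = 0.0267, adjusted p = 0.785 with an estimated correlation, with medians of 0.31 in BY003, 0.09 in BY008 and 0.93 in BY012. The call was lost once array medians were subtracted (adjusted p = 0.0551) or without BY012 (0.125, and from 0.00382 to 0.125 over the alternatives with the preset correlation). Of the sulfur genes, 6 of 23 fell (6 adjusted over the list alone), median -1.12, adjusted p = 0.0145, adjusted p = 0.785 with an estimated correlation, lost without BY008 (adjusted p = 0.204, and from 0.000229 to 0.204 over the alternatives with the preset correlation). MET28 (-3.12 ± 0.47) and MUP3 (-2.91 ± 0.49) fell, and the list had medians of -0.68 in BY003, -1.91 in BY008 and -0.35 in BY012. Of the iron genes, by contrast, 8 of 12 rose (9 adjusted over the list alone), median 1.09, adjusted p = 0.00122, adjusted p = 0.664 with an estimated correlation, with the reductase gene FRE1 at 2.39 ± 0.37 (adjusted p = 0.0517 without BY003). The iron medians were 1.03 in BY003, 1.61 in BY008 and 0.53 in BY012. Of the pyrimidine genes, 4 rose and 1 fell out of 10 (4 and 1 adjusted over the list alone), median 0.36, adjusted p = 0.126, adjusted p = 0.722 with an estimated correlation. Of the mitochondrial ribosomal protein genes 36 rose and 1 fell out of 66 (42 and 1 adjusted over the list alone), median 0.47, adjusted p = 9.65e-10, adjusted p = 0.663 with an estimated correlation, with a rise of RSM19 (1.20 ± 0.24). Of the ribosome biogenesis genes, 2 of 128 rose (0 adjusted over the list alone), median 0.22, adjusted p = 0.000784, adjusted p = 0.828 with an estimated correlation. Of the cytosolic ribosomal protein genes, 1 of 127 rose (0 adjusted over the list alone), median 0.18, adjusted p = 0.000689, adjusted p = 0.828 with an estimated correlation.

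Nitrogen genes fell further in this interval. Of the nitrogen catabolite repression list, 3 rose and 29 fell out of 40 (3 and 30 adjusted over the list alone), median -1.19, adjusted p = 3.25e-08, adjusted p = 0.336 with an estimated correlation. Examples are UGA1 (-3.42 ± 0.32), DAL4 (-3.16 ± 0.47) and MEP2 (-2.82 ± 0.15). Of the allantoin and urea genes, 1 rose and 7 fell out of 10 (1 and 8 adjusted over the list alone), median -1.47, adjusted p = 0.00682, adjusted p = 0.664 with an estimated correlation, among them DAL5 (-2.78 ± 0.24) and DAL7 (-2.66 ± 0.36), with medians of -2.05 in BY003, -1.58 in BY008 and -0.82 in BY012. Of the central nitrogen genes 4 of 5 fell (4 adjusted over the list alone), median -0.90, adjusted p = 0.0279, adjusted p = 0.336 with an estimated correlation. Among them were GDH2 (-1.60 ± 0.45), GDH3 (-1.31 ± 0.20), GLT1 (-0.91 ± 0.19) and GLN1 (-0.78 ± 0.23). Of the proline genes, 2 of 4 fell (2 adjusted over the list alone), median -0.47, adjusted p = 0.535, adjusted p = 0.828 with an estimated correlation: PUT4 was lower (-1.76 ± 0.30), and PUT1 stood at 0.07 ± 0.24 (adjusted p = 0.837). GAP1 was called at -0.89 ± 0.23, DAL80 at -0.70 ± 0.21, GAT1 at -0.72 ± 0.21 and GLN3 at 0.98 ± 0.19. DUR3 was at -1.36 ± 0.54 (adjusted p = 0.0812, and 0.0420 with experiment as a block), and GDH1 (-0.54 ± 0.38), CIT2 (-0.36 ± 0.22), URE2 (0.10 ± 0.15), GCN4 (-0.17 ± 0.11) and ACT1 (-0.21 ± 0.14) did not pass the test. Without BY003 the calls of GAP1 (0.241), PUT4 (0.0602), DAL80 (0.173), GAT1 (0.139), GLN1 (0.146), GLN3 (0.0929), GLT1 (0.127), GDH2 (0.152) and GDH3 (0.0624) were lost (adjusted p in parentheses). Without BY008 those of GAP1 (0.0755), DAL80 (0.209), GAT1 (0.136), GLN1 (0.0972) and GDH2 (0.0801) were lost, and without BY012 that of GLN1 (0.0555). Once array medians were subtracted, DAL80, GAT1 and GLN1 were not called.

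Of the stress response genes 31 of 38 fell (35 adjusted over the list alone), median -2.15, adjusted p = 1.54e-12, adjusted p = 0.663 with an estimated correlation. Examples are CYC7 (-4.04 ± 0.35) and HXK1 (-3.24 ± 0.16). Of the proteasome genes, 27 of 33 fell (31 adjusted over the list alone), median -0.89, adjusted p = 8.06e-09, adjusted p = 0.677 with an estimated correlation. Among them were PRE3 (-2.22 ± 0.27) and PRE1 (-2.04 ± 0.26). Of the autophagy genes, 0 rose and 11 fell out of 19 (1 and 15 adjusted over the list alone), median -0.86, adjusted p = 0.000752, adjusted p = 0.664 with an estimated correlation. Examples are ATG2 (-3.07 ± 0.28) and ATG9 (-2.27 ± 0.31). Of the TCA cycle genes, 9 of 15 fell (10 adjusted over the list alone), median -1.28, adjusted p = 2.35e-05, adjusted p = 0.494 with an estimated correlation. Among them were CIT1 (-1.87 ± 0.25), KGD2 (-1.72 ± 0.16) and SDH3 (-1.41 ± 0.19). All 6 hexose transporter genes fell (6 adjusted over the list alone, median -2.30, adjusted p = 0.000117, adjusted p = 0.233 with an estimated correlation), HXT7 (-3.12 ± 0.44), HXT2 (-3.01 ± 0.23) and HXT3 (-2.18 ± 0.15) among them, though the probe set of HXT7 may read more than 1 transcript. Of the ergosterol genes 9 of 23 fell (12 adjusted over the list alone), median -0.45, adjusted p = 0.00700, adjusted p = 0.722 with an estimated correlation, with a fall of ERG28 (-2.11 ± 0.24). Of the glycolysis genes, 2 of 15 fell (2 adjusted over the list alone), median -0.17, adjusted p = 0.0448, adjusted p = 0.772 with an estimated correlation. The call was lost without BY003 (adjusted p = 0.0679), BY008 (0.0667) or BY012 (0.0968) and once array medians were subtracted (0.104, and from 0.0452 to 0.104 over the alternatives with the preset correlation), with the enolase gene ENO1 at -0.99 ± 0.13. CLN3 was called at -1.07 ± 0.30 (adjusted p = 0.219 without BY003). With experiment as a block the G2 to M list was called as higher (adjusted p = 0.0324, 5 of 9 rose), and the core histones (adjusted p = 0.0328, 4 of 7 fell) and retrograde genes (adjusted p = 0.0486, 4 of 9 fell) as lower. Without the block their adjusted p values were 0.0856, 0.0829 and 0.0856, and with an estimated correlation they were adjusted p = 0.785, 0.785 and 0.677. Over the alternatives with the preset correlation they ran from 0.00226 to 0.199, from 0.0117 to 0.150 and from 0.0486 to 0.129, in that order.

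This comparison called 1817 genes, 718 higher and 1099 lower, at an all-gene median of -0.01. Of all genes, called or not, 74.0% had 1 sign in all 3 experiments. The split became 940 higher and 991 lower once array medians were subtracted, and 1003 higher and 794 lower after quantile normalization. Camera called 18 of the 39 lists, 7 higher and 11 lower, and fry called 17. With an estimated correlation camera called 0 (adjusted p from 0.233 to 0.858), and 5 had an unadjusted p under 0.05. Without BY003, 388 genes were called and 65 of the 122 called named genes were lost, and without its 24 min array 1108 genes were called. Those called higher numbered 83 without BY003 and 372 without BY008.

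The calls at 7 and at 24 min were set beside each other. Of the genes called at both times, 832 were higher and 1571 lower at both, against 219.1 and 873.3 for independent lists. Both comparisons share the 3 arrays at -10 min, too few to give each comparison 2 of its own. The values for independent lists do not allow for this, and part of the excess may come from the shared arrays. Log2 fold changes at both times correlated over genes with r = 0.82, against 0.498 in 100 simulations of unchanged groups sharing those arrays, and their covariance was 1.16 against 0.0309. In all, 2403 genes were called the same way at both times, or 1219 without BY003, 14 were higher then lower, and 20 lower then higher.

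The times with 1 array were described as differences from the -10 min array of the same experiment, BY008. At 3 min, NSR1 was already 3.84 higher on the log2 scale, and RFU1 (3.40), RRN11 (2.83) and DBP2 (2.83) were among the 5 largest rises. RRN11 encodes a factor for ribosomal RNA transcription. The ribosome biogenesis list stood at 1.66 relative to all genes at 3 min, 3.04 at 7 min, 3.45 at 24 min, 2.83 at 56 min and 2.28 at 120 min. RNA polymerase I and III genes went from 0.95 at 3 min to 2.57 at 24 min, 2.27 at 56 min and 1.79 at 120 min, and the cytosolic ribosomal protein genes from 0.12 to 0.74, 0.58 and 0.69. Permeases under the SPS sensor stood at 0.45 at 7 min, 2.32 at 14 min and 3.53 at 24 min, and AGP1 at 0.21, 3.88, 3.85 and 4.59 at 7, 14, 56 and 120 min. The hexose transporter list was at 1.30 at 7 min, 0.68 at 14 min and -1.07 at 24 min.

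The nitrogen catabolite repression list went from -0.29 at 3 min to -2.02 at 14 min, -2.25 at 56 min and -1.77 at 120 min. DAL80 stood at -2.61 and MEP2 at -0.48 at 7 min, against -3.85 and -3.39 at 14 min. MEP2 started at a mean log2 intensity of 14.81, close to the highest value of 15.14, so its small early change may be compressed and the timing of these genes cannot be compared. GAP1 stood at -3.08 at 14 min, -2.08 at 24 min, -2.13 at 56 min and -0.64 at 120 min. Part of its return was thus seen at 24 and 56 min, against a single array at 14 min. MEP2 stood at -3.45 at 24 min, -3.03 at 56 min and -0.93 at 120 min. The further return of GAP1 and most of that of MEP2 rest on the 120 min array alone. PUT1 stood at -2.48 and GDH2 at -3.29 at 56 min, and at -3.04 and -3.28 at 120 min. Among brighter genes the largest falls at 10 min were DIP5 (-4.05), DAL80 (-3.49) and DSD1 (-3.31), and at 120 min OPT2 (-4.89), APE1 (-4.05) and PUT4 (-3.55). The stress response list was at -2.90 at 24 min, -1.93 at 56 min and -1.16 at 120 min, the proteasome list at -1.19, -0.50 and -0.09, and the autophagy list at -2.04, -0.90 and -1.15. S phase entry genes stood at -1.67, -2.14 and -0.42. At 120 min the array also had 187 probe sets raised above all others, 11 of them S. cerevisiae genes.

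**Figure D3:**
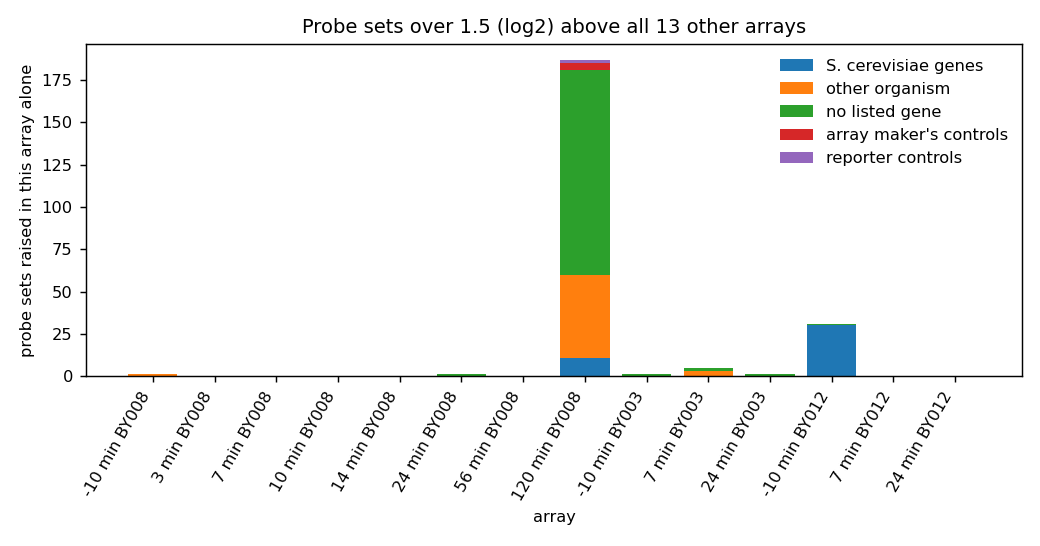
Number of probe sets per array lying more than 1.5 (log2) above all 13 other arrays, by class of probe set. The 120 min array has 187 and the -10 min array of BY012 has 31.

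Of 5449 genes, 242 were at least 2-fold higher and 10 at least 2-fold lower at 3 min in BY008, 574 and 1058 at 10 min, 614 and 1247 at 14 min, 675 and 957 at 56 min, and 465 and 666 at 120 min. Relative to the all-gene median the counts were 252 and 9, 784 and 617, 861 and 819, 816 and 739, and 590 and 456, so at the last 4 of these times the balance turned from mostly lower to mostly higher. Against the mean of the 3 -10 min arrays, and with the spread of the replicated times assumed for each lone array, limma called 66 genes at 3 min (64 higher), 2231 at 10 min, 2488 at 14 min, 2061 at 56 min and 1557 at 120 min. These calls say that the 1 array differs, and cannot tell its time from anything else particular to it, so no change over time rests on them. At 3 min, where 7 genes were called at an adjusted p under 0.01, 473 had an unadjusted p under 0.05.

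**Figure D4:**
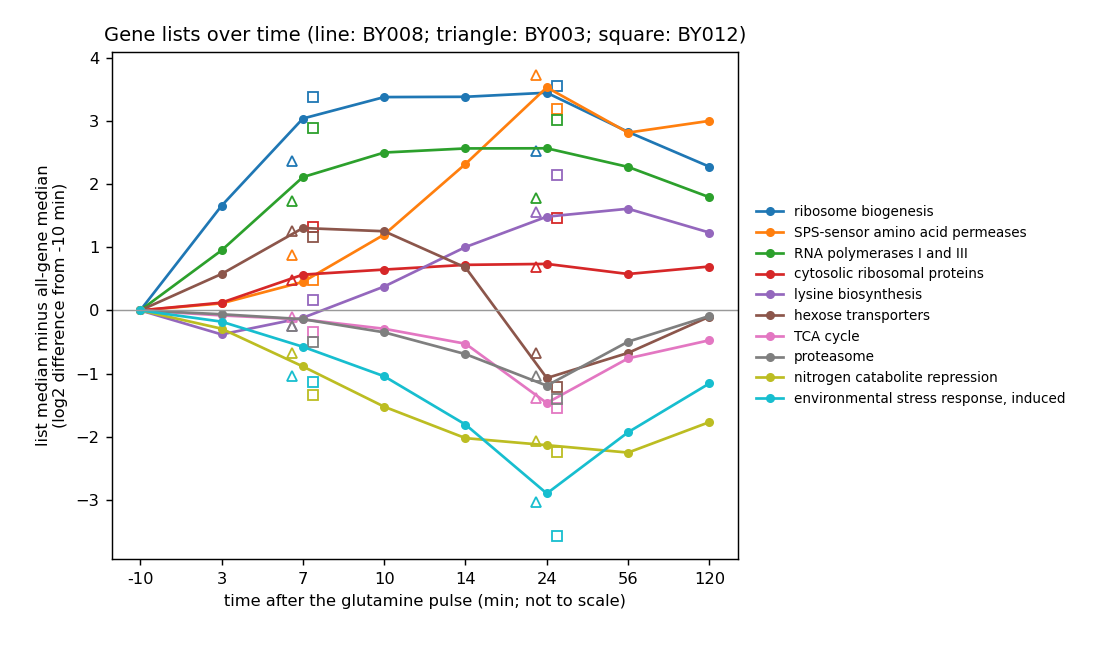
Median log2 difference from -10 min of 10 gene lists minus the all-gene median (vertical axis) against time (spacing not to scale), with lines for BY008 and open symbols for BY003 and BY012. Ribosome biogenesis stands at 1.66 at 3 min and 3.45 at 24 min, and hexose transporters at 1.30 at 7 min and -1.07 at 24 min.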

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

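The tests of the share of raised probe sets, of a brighter background, of a wrong label, of a kept culture state, of a scaling factor, of RNA integrity over time and of the hybridisation spikes were chosen only after the result was seen. For 34 genes the calls at 7 and 24 min went in opposite directions, and 12 of them fall under the rule for naming genes. Since they were chosen for opposite calls, a difference between 24 and 7 min follows from the choice, and its test adds nothing. Its size was -4.69 for MTH1, -4.51 for COS111, -4.42 for YKR075C, -3.12 for MET28, -3.01 for HXT2, -2.18 for HXT3 and -1.48 for HXT1, which were higher at 7 and lower at 24 min than at -10 min. It was 3.63 for HSP30, 3.56 for SRL3, 2.64 for LYS20, 2.51 for LYS1 and 0.94 for MRP7, which were lower and then higher. The opposite calls at 7 and 24 min often did not hold after rescaling or with fewer arrays (limma). Of the 34 genes they were kept by 33 with experiment as a block and 31 with trend and robust options. They were kept by 14 with array medians subtracted, 13 with quantile normalization, 8 without BY003, 12 without BY008 and 11 without BY012. Leaving out an experiment leaves fewer arrays, which lowers such counts by construction. Of the 12 named genes, only YKR075C and HXT2 kept them in each of these settings. The 7 min call was lost without BY003 for MTH1 (adjusted p = 0.0795), COS111 (0.0760), SRL3 (0.0552), HXT3 (0.0765), HXT1 (0.144), LYS20 (0.137), LYS1 (0.178) and MRP7 (0.0980). Without BY008 it was lost for COS111 (0.0586), HSP30 (0.0581) and MET28 (0.0986). Without BY012 it was lost for HSP30 (0.204), MET28 (0.223), LYS20 (0.0849), LYS1 (0.152) and HXT1 (0.0612). With array medians subtracted it was lost for HSP30 (0.0596), LYS1 (0.153) and MRP7 (0.0560), and with quantile normalization for HSP30 (0.0891), LYS1 (0.122) and MRP7 (0.0624). The 24 min call was lost without BY008 for MET28 (0.0611), HXT1 (0.161) and MRP7 (0.0751), for HXT1 with array medians subtracted (0.121), and for MRP7 without BY003 (0.180) and without BY012 (0.122). Data outside the tested genes also moved: 379 of 1747 probe sets of the other yeast were called at 24 against -10 min (313 higher, 66 lower), 51 of them among the 88 above the dim bound. Of the 3470 probe sets with no listed gene, 901 were called (643 higher, 258 lower), 269 of them among the 393 above that bound. The median of the other yeast's probe sets rose as well, from 4.70 ± 0.07 at -10 min to 4.86 ± 0.04 at 24 min (SD, n = 3 arrays). Part of the calls of that yeast's probe sets may thus go with a shift of the whole class.

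Splits of the arrays were compared with the real grouping. For 7 against -10, 24 against -10 and 24 against 7 min, the real split alone (1 of 10) reached 2857, 3756 and 1817 genes, the highest other was 0 each time (limma), and 10 splits are too few for a share under 0.05. The other splits that part all 3 experiments also gave 0. For the F test, 1 of 100 drawn splits of the 280 possible, the real one, called as many as 4001 genes, the highest other was 2031, and this share is under 0.05. Most drawn splits did not spread all 3 experiments over the 3 groups. Those that did were too few for a share under 0.05 among them.

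The 120 min array of BY008 had 187 probe sets more than 1.5 above all 13 other arrays on the log2 scale, against at most 31 in any other array. They included 2 of 47 reporter controls, at 9.15 and 7.96 against at most 5.14 and 5.37 elsewhere. A brighter background is argued against: the median of other-organism probe sets lay 0.00682 above the highest other array. A further 4 Affymetrix controls were raised. Of 5217 probe sets not given to an S. cerevisiae gene 170 were raised, against 11 of 5498 that were (odds ratio 16.8, 95% interval 9.14 to 34.4). RNA of another organism or strain in that sample is a candidate explanation, but this ratio does not single it out. Other-organism probe sets were dim on that array (median log2 4.91 against 10.94 for genes), so any added signal passes the gap of 1.5 more easily on them. Whether RNA of the other yeast on the array was present cannot be told. The 7 ACT1 and GPD3 control probe sets of that yeast had a median change of 1.09, between the bounds set for either answer, and a largest change of 3.27.

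The -10 min array of BY012 stood apart, with sulfur genes at -1.98 and stress response genes at 0.90 against the other -10 min arrays. A label from another time is argued against, since its highest correlation (0.942) was with another -10 min array, against 0.892 with any other time. Lower RNA integrity is not settled by its mean 3-prime minus 5-prime difference of 1.95. This lay within the 1.44 to 1.98 of the other arrays, but only the -10 min array of BY003, at 1.98, lay higher. That BY003 array had 6 genes at least 4-fold above and 1 at least 4-fold below both other -10 min arrays. If 1 culture was sampled over time, a culture state kept at 7 min may account for part of the deviation of BY012. Its deviations at -10 and 7 min correlated with r = 0.561 over genes, which are not independent replicates, and those at -10 and 24 min with 0.08. Since r was 0.63 in BY008 and 0.08 in BY003, this remains a hypothesis.

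The median gene changed by -0.33 from -10 to 24 min. Whether a single scaling factor per array accounts for this is not settled by the brightness of genes. Of 3 equal groups of genes by brightness, the brightest changed by 0.734 more than the dimmest (-0.01 against -0.74). Brightness was averaged over arrays before and after the pulse, so genes that fell tend to sort into the dimmest group. Changes of the brightest genes may also be compressed. Loss of RNA integrity is argued against, because the 3-prime minus 5-prime difference changed by -0.220 (SD 0.11 over 3 experiments), a fall rather than a rise. A fall shared with the hybridisation spikes is argued against at 24 min only, where 9 spike probe sets changed by 0.169 (SD 0.0851). At 7 min the spikes were lower, at a mean log2 of 12.03 ± 0.20 against 12.29 ± 0.17 at -10 min (SD, n = 3 arrays). The median gene also changed by -0.33 from -10 to 7 min, so a shared fall stays open at that time. The median of other-organism probe sets was 0.167 higher at 24 than at -10 min (mean of 3 arrays each), while the median gene fell. A scaling factor and a change of the RNA pool by the cells both stay open as hypotheses, with other technical steps untested.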

How the results depend on the processing

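With experiment as a replicate block, 3302, 3972 and 2252 genes were called in the 3 comparisons and 4321 by the F test. The block gained the calls of 7 list comparisons, given in the results, and of CIT2 (7 min), HXK2 (7 min), VAS1 (24 against 7 min) and DUR3 (7 min and 24 against 7 min). It lost those of MET32 (24 min) and TRP2 (24 against 7 min), and it changed no other call of a list or named gene. Under a random block, the scaling alternatives, the dim filter, trend and robust options, the mean over probe sets and the added probe sets (chosen after seeing the data), every total count of genes stayed within 1.5 times its main value. Counts by direction moved further: lower calls at 10 min went from 1522 to 953 (array medians subtracted) and 941 (quantile), and those at 14 min from 1660 to 1102 (quantile). Higher calls at 24 against -10 min went from 1312 to 2015 (added probe sets). Lower calls at 3 min went from 2 to 6 (quantile), 1 (trend and robust) and 0 (block). For the counts that moved further the cause was not tested, except that stricter thresholds and fewer arrays lower a count by construction. At an adjusted p under 0.01, 1820 genes were called at 7 against -10 min, 921 at 24 against 7 min, 7 at 3 min, 1223 at 10 min, 1518 at 14 min, 1126 at 56 min and 542 at 120 min. With a log2 change of at least 1 as well, 1308, 2296 and 799 were called in the 3 comparisons and 2450 by the F test over -10, 7 and 24 min. With an estimated correlation camera called 0, 0 and 0 lists (3, 2 and 5 at an unadjusted p under 0.05; fry called 21, 32 and 17). Leaving out 1 experiment or array gave 1373 (without BY003) to 2727 genes at 7 against -10 min, 2786 (without BY003) to 3655 at 24 against -10 min, 388 (without BY003) to 1594 at 24 against 7 min (1108 without the 24 min array of BY003, and higher calls from 718 to 83 without BY003, 372 without BY008, and 347, 462 and 440 without the 24 min array of BY003, its 7 min array and the 7 min array of BY008), 2476 (without BY003) to 3929 for the F test, and 1219 (without BY003) to 2066 for the overlap. A time left with 2 arrays was assumed to vary like the others.

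No called value of a named gene or gene list turned direction. Turns were not counted over all other genes. Among those, SUC2 was called at -0.40 at 24 against -10 min and stood at 0.14 after quantile normalization, where it was not called. Values that were not called turned in at least 1 setting for 8 of 462 named genes and comparisons and for 7 of 117 list comparisons, and the cause was not tested. With array medians subtracted, GCN4 was at 0.196 (7 min) and 0.110 (24 min), ACT1 at 0.0143 (7 min) and GDH1 at 0.174 (24 min). Over the arrays left out, values ran from -0.0663 to 0.196 for central nitrogen genes, from -0.172 to 0.120 for lysine genes (-0.127 without the -10 min array of BY012) and from -0.0692 to 0.00930 for meiosis genes at 7 min (-0.0232 without BY003, -0.0332 without BY008). At 24 min they ran from -0.803 to 0.909 for sulfur genes (-0.481 without the -10 min array of BY012), from -0.390 to 0.0713 for G2 to M genes and from -0.212 to 0.364 for mating type a genes (-0.156 without BY012), and at 24 against 7 min from -0.0813 to 0.185 for the last. For genes they ran from -0.218 to 0.556 for AGP1, from -0.0209 to 0.0180 for GCN4 and from -0.117 to 0.663 for CLN3 at 7 min, from -0.458 to 0.239 for GDH1 at 24 min, and at 24 against 7 min from -0.0147 to 0.173 for PUT1 and from -0.0266 to 0.247 for URE2. Signal over background limits 132 of the 5449 genes, whose mean log2 value lies at or under 6.11, the bound that 95% of other-organism probe sets stay below.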

Other observations

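The list of glucose-repressed genes was tested only after part of its result was seen, and the list of Slt2 targets was written before its result but after SLT2, PRM5 and YPS3, which it leaves out, had been seen. Targets of the Slt2 kinase, which acts in cell wall maintenance, were higher at 24 than at 7 min: 9 of 15 measured rose and 0 fell (limma), with a median of 1.33 relative to all genes (camera, adjusted p = 6.93e-06, and adjusted p = 0.445 with an estimated correlation). The medians were 1.49 in BY003, 1.13 in BY008 and 1.12 in BY012. At 24 against -10 min 7 rose, with a median of 1.33 (adjusted p = 0.00183, and adjusted p = 0.534 with an estimated correlation), and at 7 against -10 min 1 rose and 2 fell, with a median of 0.02. In BY008 the median went from -0.08 at 3 min and 0.54 at 14 min to 1.26 at 24 min, 1.53 at 56 min and 0.91 at 120 min. That the pathway is active late after the pulse is a hypothesis, found and tested on the same data.

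Genes under glucose repression were lower at 24 than at 7 min: 1 rose and 9 fell of 22, with a median of -0.946 relative to all genes (camera, adjusted p = 0.00443, and adjusted p = 0.743 with an estimated correlation). The list leaves out CAT8 and MTH1, which were seen first. At 24 against -10 min 1 rose and 16 fell, with a median of -1.23 (adjusted p = 0.111), and -2.23 in BY012, whose -10 min array stood apart. At 7 against -10 min 2 rose and 3 fell, with a median of -0.07. In BY008 the median was -0.61 at 14 min, -0.80 at 56 min and -0.61 at 120 min.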
